A study of Xenopus laevis with 12 samples.

How the data were processed

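Gene expression was measured in whole single embryos of the frog Xenopus laevis at stage 11.5, in the later part of gastrulation, with a 1-colour Affymetrix expression array. Per the labels, mRNA was injected at the 8-cell stage. The labels put 6 embryos in a group given GFP mRNA, the control, and 6 in a group given Nkx2-5 mRNA together with GFP mRNA. Total RNA was extracted from each embryo and 100 ng was labelled with biotin in a 2-cycle protocol, per the labels' protocols, so each of the 12 arrays holds 1 embryo. The labels name a single experiment for all 12 embryos and do not say whether the embryos came from the same parents, so p-values measure the spread between these embryos.

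The deposited values are probe set intensity values, here called signals, on a linear scale, which the authors computed with MAS5, per the submitters' processing notes. Its version, the scaling target and the detection calls are not given in the sources used here. The scale was read from the values. All were positive, and the mean without the lowest and highest 2% of probe sets lay at 1000.1 on each array. The table held 15611 probe sets. Of these, 120 control probe sets of the manufacturer were left out of the tests and 15491 were tested, with no filter on low values. No depth applies to an array, and the number of arrays limits the precision. Median signals lay between 302 and 346 and the 10th percentile between 16.9 and 24.3, and differences of dim probe sets are compressed by the pseudocount.

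Signals were transformed as log2(signal + 16), and a fold difference is on that scale, which understates the change of dim probe sets. No further scaling was applied. The comparison of Nkx2-5+GFP with GFP embryos was fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, 2-sided, with 10 residual degrees of freedom. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all 15491 probe sets, and a probe set was called changed at an adjusted p under 0.05. The SE given beside a log2 difference is limma's moderated standard error. Single values such as the nkx2-5 signals were also compared with a 2-sided exact permutation test over all 924 assignments of the 12 embryos to groups of 6, which cannot give a p below 0.00216. Plots were drawn with matplotlib 3.10.9.

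Gene names come from a table of the array's annotation, brought up to date by gene number with a RefSeq gene table of the assembly Xenopus_laevis_v10.1, of which only names were used. One gene was named for 9304 probe sets, several for 195, from which no name was taken, and none in that table for 5992, which are unnamed here. The gene number of 9227 probe sets was found in the RefSeq table, and 2 symbols were updated. Xenopus laevis carries a pair of copies of many genes, called homeologs and marked L and S, and each copy was treated as its own gene. Probe sets whose identifier ends in s_at or x_at can detect more than 1 transcript.

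The 18 gene lists were fixed before the data were examined: cardiac, skeletal muscle and paraxial mesoderm, marginal zone mesoderm and FGF, organizer and dorsal, ventral and BMP, endoderm, neural plate and neural crest, epidermis and ciliated cells, blood and endothelium, maternal and germ plasm, cell cycle, p53 and apoptosis, heat shock and stress, Notch, Wnt, retinoic acid, cell adhesion and movement, and ribosomal proteins. Some genes stand in more than 1 list. Older symbols counted where the tables hold them. Each gene was represented by its probe set of highest mean log2 value, which left 7531 genes as the background. Lists were tested with camera of limma with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 18 lists, and again with the correlation estimated from the data. Counts of members use the adjustment over all probe sets, and a second count was adjusted over the list alone. Beside a list's counts, the embryo whose removal gave the lowest or highest count is named, the first in order where several gave the same. A named embryo need therefore not be the only one.

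The rule for named genes was also fixed beforehand. It takes all nkx2-5 probe sets and, among changed probe sets with 1 named gene and a mean in the higher group at or above the median of all probe sets, which was 8.41 on the log2 scale, the 12 largest rises and the 12 largest falls. It adds up to 4 changed members of each list by smallest p and up to 2 members that did not pass. The unnamed probe set of largest difference, the control probe sets, the homeolog pairs and the genes named with the axis score were chosen after their values were seen.

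The alternatives fixed beforehand were pseudocounts of 1 and 64, leaving out the dimmer probe sets, quantile normalization, scaling by the array median, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, leaving out each embryo in turn, and for lists an estimated correlation, the rotation test fry and the mean of all probe sets of a gene. Covariates added after the data were seen are the score on the first axis of variation among the GFP embryos and the log2 ratio of the 3' to the 5' beta-actin control probe set. The first axis was computed on the brighter 7746 probe sets, from the GFP embryos alone, and all 12 embryos were given a score on it. Its direction was set so that its weights correlated positively with the group difference.

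The procedure was tested on simulated data made from the real means and spreads of the 15491 probe sets, with 200 changed in each of 5 runs. It recovered 31.3% of the changes of 0.5 on the log2 scale, 75.2% of those of 1 and 96.4% of those of 2, and 5.29% of its calls were false. No probe set was called in simulated comparisons without a change. A list of 30 genes shifted by 0.5 was found in 5 of 5 runs. The simulated noise was independent between probe sets, while genes of the real embryos varied together. The simulation therefore does not show how camera or the share of false calls fare under such correlation.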

Results

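Whole-embryo transcript levels were compared between 6 Xenopus laevis embryos given GFP mRNA and 6 given Nkx2-5 mRNA with GFP mRNA, injected at the 8-cell stage and collected singly at stage 11.5. Nkx2-5 is a homeodomain transcription factor known for its role in heart formation, and GFP is the jellyfish fluorescent protein that served as the control. The comparison asks which transcripts differ when Nkx2-5 mRNA is supplied before gastrulation, in a study whose title speaks of putative targets of this factor. Each embryo was measured on its own array, and signals of all 12 arrays correlated with those of another array at up to 0.982, so no array repeated another.

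Embryos given Nkx2-5 mRNA had higher signals for the epidermal genes itln1.L and krt12.4.S and lower signals for the Nodal-related gene nodal3.1.L and the mix1 homeobox genes. itln1.L, which encodes an intelectin secreted by epidermal cells, rose from 582 ± 162 to 3516 ± 1634 (SD, n = 6 each), a log2 difference of 2.49 (SE 0.25, limma adjusted p = 0.000193), and the groups did not overlap. nodal3.1.L, a Nodal-related ligand of the organizer, fell by 2.43 on the log2 scale (SE 0.26, limma adjusted p = 0.000223), from 781 ± 314 to 132 ± 55.3 (SD, n = 6 each). Both homeologs of mix1, a homeobox gene induced by Nodal signals in mesendoderm, fell as well, by 1.23 for mix1.L and by 1.29 for mix1.S. myf5.L, a regulator of muscle determination, rose by 1.13 on the log2 scale.

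**Figure D1:**
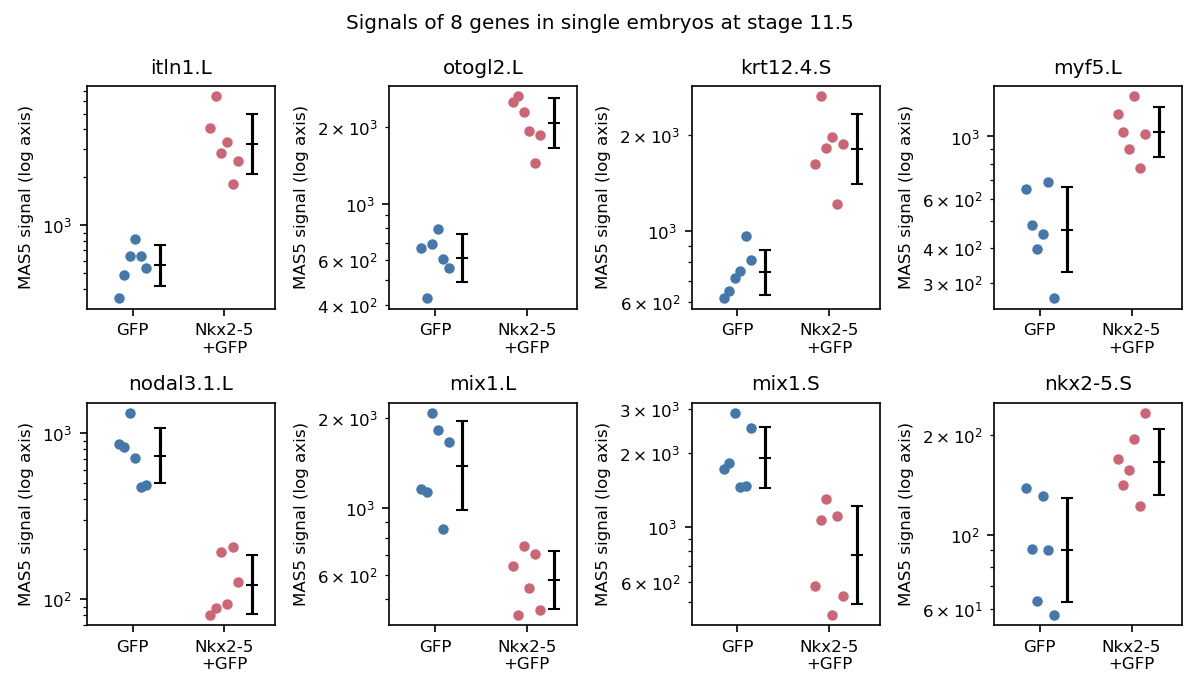
MAS5 signals of 8 genes on log axes, 1 point per embryo, with GFP embryos in blue and Nkx2-5+GFP embryos in red; black bars are the mean ± SD of the log2 signals. The GFP and Nkx2-5+GFP points do not overlap for itln1.L, otogl2.L, krt12.4.S, myf5.L, nodal3.1.L, mix1.L and mix1.S, and they overlap for nkx2-5.S.

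The array carries a pair of probe sets for nkx2-5.S. The probe set for which the difference was larger rose from 95.0 ± 33.4 to 169 ± 39.7 (SD, n = 6 each), a log2 difference of 0.77 (SE 0.21, limma adjusted p = 0.0431, exact permutation p = 0.00866). In the other probe set the signals were 93.7 ± 20.7 and 140.5 ± 24.8, a log2 difference of 0.52 that did not pass after adjustment (limma adjusted p = 0.0731, exact permutation p = 0.00433). The labels do not say which part of the transcript was injected, so these probe sets need not detect it. The call for the first nkx2-5.S probe set was lost without GFP embryo 2, 3 or 6 and without Nkx2-5+GFP embryo 1, 2, 3, 4 or 6. It was also lost without the intensity trend, with array weights and with the replicate number as a block, and limma's adjusted p ranged from 0.0268 to 0.106 over the alternatives fixed beforehand. The call was lost as well when the fit held the beta-actin 3' to 5' ratio or a score of the shared variation among GFP embryos.

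Over all probe sets, limma called 988 of 15491 changed, or 6.38%, with 483 higher and 505 lower in Nkx2-5+GFP embryos. Of these, 606 carried 1 named gene. A log2 difference of at least 1 was reached by 130, of which 114 were higher and 16 lower, and by 213 without GFP embryo 5, 66 with a pseudocount of 64 and 45 without the dimmer probe sets. The groups did not overlap in 463 probe sets, 2.99% of those tested where chance gives 0.216%. The count of changed probe sets, 988 in the main fit, was 760 without GFP embryo 1 and moved by more than 1.5 times without most other embryos. It was 558, 330, 463, 1484 and 402 without GFP embryos 2, 3, 4, 5 and 6, and 285, 502, 519, 1485 and 510 without Nkx2-5+GFP embryos 1, 2, 4, 5 and 6. Without the intensity trend limma called 437. Of the 72 named probe sets that passed, 28 passed in each alternative fixed beforehand that tested them. Dim ones, nodal3.1.L among them, were not tested without the dimmer probe sets. Another 10 lost their call in most alternatives, namely bix1.2.S, cdh11.S, cdh3.L, hes2.L, mdm4.S, nkx2-5.S, pax3.S, rbm24.L, tent2.S and tmem169.L. For 17 of the named genes the array holds 25 other probe sets, of which 4 were called, each in the direction of the named probe set, and 21 did not pass, 2 of these with the opposite sign.

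Among the other large rises, otogl2.L, an otogelin-like gene, rose by 1.72 in a probe set with a GFP signal of 625 ± 127 (SD, n = 6), while a brighter otogl2.L probe set, at 1302 ± 177 (SD, n = 6), differed by 0.27 and did not pass (limma adjusted p = 0.118). olfm4.L, which encodes a secreted olfactomedin, rose by 1.76, liph.L, a lipase gene, by 1.39, anxa2.S, an annexin gene, by 1.32 and krt12.4.S, a keratin gene, by 1.26. cd81.L, which encodes a tetraspanin, rose by 1.68 and kit.S, a receptor tyrosine kinase gene, by 1.27, while the other kit.S probe sets differed by 0.22 and 0.28 and did not pass. c3.L, a complement component, rose by 1.60 and sult6b1.5.L, a sulfotransferase gene, by 1.23. The transcription factor genes gbx2.2.L and pax3.S, both active in the forming neural plate border, rose by 1.91 and 1.66, with GFP embryos spread widely at 191 ± 155 and 320 ± 275 (SD, n = 6). Over the alternatives fixed beforehand, limma's adjusted p reached 0.0797 for gbx2.2.L and 0.106 for pax3.S. The other gbx2.2.L probe set differed by 0.55 and did not pass (limma adjusted p = 0.362). The brighter L copy, pax3.L, differed by 0.42 and did not pass (limma adjusted p = 0.0955).

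Under the rule for named genes, which leaves out dimmer probe sets, the 12 largest falls held, after nodal3.1.L and mix1, bix1.2.S. This gene, another mix-type homeobox gene of endoderm, fell by 0.92 on the log2 scale, a call lost in most alternatives fixed beforehand (limma adjusted p up to 0.106). cebpg.L, a bZIP factor gene, fell by 1.13, zfp36l2.2.L, which encodes a protein that destabilises mRNA, by 0.92 and cdc45.L, a DNA replication factor gene, by 0.92. fignl1.L fell by 0.95, ccdc77.L by 0.93, rilp.S by 0.93, tmem169.L by 0.90 and klhdc10.L by 0.90.

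The list of epidermis and ciliated cells held 42 measured genes, of which 12 rose, 0 fell and 30 did not pass. Adjusted over the list alone, 17 rose and 2 fell. The list stood above other genes in limma's camera (adjusted p = 6.99e-06, mean log2 difference 0.28), and its adjusted p was 0.121 with an estimated correlation. Besides itln1.L and krt12.4.S, the keratin genes krt7.L and krt12.5.S rose by 0.65 and 0.90. The claudin gene cldn6.1.S, at a log2 difference of -0.27, did not pass. Between 7 members, without GFP embryo 3, and 12 rose when 1 embryo was left out.

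The 29 measured genes of skeletal muscle and paraxial mesoderm had 5 that rose, 0 that fell and 24 that did not pass, and 9 rose when adjusted over the list alone. The list stood above other genes (camera adjusted p = 4.48e-05), and the adjusted p was 0.121 with an estimated correlation. After myf5.L, the largest changes by p were in myod1.L, another muscle determination gene, which rose by 0.84, and msgn1.L, a gene of presomitic mesoderm, which rose by 1.05. rbm24.L, an RNA-binding protein gene of muscle, rose by 0.89. The S copy, myod1.S, differed by 0.67 and did not pass. Without GFP embryo 2, 3, 4 or 6 or Nkx2-5+GFP embryo 1, 2 or 4, 1 member rose, and without GFP embryo 5, 7 did.

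Cardiac genes, 40 measured, did not stand apart as a list (camera adjusted p = 0.199, and adjusted p = 0.264 with an estimated correlation). Of them 2 rose, 1 fell and 37 did not pass, and adjusted over the list alone 4 rose and 1 fell. irx4.L, known from ventricular myocardium, rose by 1.71 from a low signal of 17.7 ± 16.3 to 90.8 ± 37.2 (SD, n = 6 each), and the other rise was nkx2-5.S itself. At this level the size for irx4.L depends on the pseudocount, and it was 2.60 with a pseudocount of 1 and 0.91 with one of 64. gata5.S, a factor of heart and endoderm, fell by 0.59 on the log2 scale. tnnc1.S, the troponin C gene of heart muscle, differed by 1.15 and did not pass (limma adjusted p = 0.0545). Without GFP embryo 2, 1 rose, and without GFP embryo 1, 0 fell. Several members were dim, such as tnnt2.L, at mean signals of 7.02 in GFP and 7.64 in Nkx2-5+GFP embryos, and tbx5.L, at 14.1 and 13.4. Others were bright, such as gata6.L at 3241 and 3096. The dim members limit what the list test can show. Without the dimmer probe sets, 0 members rose and 1 fell (camera adjusted p = 0.466). The mean log2 difference of the list was then -0.16 in place of 0.11.

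The endoderm list had 34 measured genes, of which 1 rose, 6 fell and 27 did not pass, and adjusted over the list alone 2 rose and 8 fell. It stood below other genes (camera adjusted p = 0.00724), with an adjusted p of 0.194 with an estimated correlation and of 0.0825 with the beta-actin 3' to 5' ratio in the fit. Besides mix1, both copies of the chemokine receptor gene cxcr4 fell, cxcr4.L by 0.60 and cxcr4.S by 0.35 on the log2 scale. sox17b.1.S, an endoderm determinant, differed by -0.33 and did not pass. Between 3, without GFP embryo 2, and 9, without GFP embryo 5, fell. Of the 34 members, 16 also stand in another list.

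In the list of marginal zone mesoderm and FGF, 34 measured, 0 rose, 3 fell and 31 did not pass. The members that fell were mix1.L, mix1.S and the Nodal ligand gene nodal6.L, which fell by 1.33 on the log2 scale, with differences from -1.88 to -0.74 over the alternatives fixed beforehand. Adjusted over the list alone, 1 rose and 4 fell. The list did not stand apart (camera adjusted p = 0.788, and adjusted p = 0.846 with an estimated correlation). The caudal-type gene cdx4.L differed by 0.71 without passing. Without GFP embryo 5, 6 members fell and 2 rose.

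The organizer list, 31 measured, had 1 rise, 1 fall and 29 that did not pass, and adjusted over the list alone 4 rose and 2 fell. The fall was nodal3.1.L, and the rise was shh.L, a hedgehog ligand of the midline, by 1.41. The BMP antagonist genes chrd.1.S and fst.L were 1.31-fold and 2.14-fold higher and did not pass. The list did not stand apart (camera adjusted p = 0.36, and adjusted p = 0.522 with an estimated correlation). Without GFP embryo 3, 0 members rose, and without GFP embryo 1, 3 rose.

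Genes of the ventral side and BMP signalling, 36 measured, had 4 that rose, 0 that fell and 32 that did not pass, and adjusted over the list alone 8 rose. The list stood above other genes (camera adjusted p = 0.00226), with an adjusted p of 0.268 with an estimated correlation. The call was also lost without the dimmer probe sets (camera adjusted p = 0.0792). gata3.S rose by 0.96 and tbx3.S by 0.88, and both are transcription factor genes active on the ventral side. id4.S, which encodes an inhibitor of bHLH factors, rose by 0.78 and dlx3.S, a homeobox gene of ectoderm, by 0.44. Without GFP embryo 3, 1 member rose, and without GFP embryo 5, 7 did.

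Neural plate and neural crest genes, 58 measured, had 2 that rose, 1 that fell and 55 that did not pass, with the same counts when adjusted over the list alone. The rises were gbx2.2.L and pax3.S, and the fall was sox3.L, by 0.51 on the log2 scale, a gene of the neural progenitor state that also stands in the maternal list. The list stood above other genes (camera adjusted p = 0.023), but its adjusted p was 0.264 with an estimated correlation, 0.0604 without Nkx2-5+GFP embryo 2 and 0.051 with quantile normalization. Without the dimmer probe sets its camera adjusted p was 0.614 and its mean log2 difference 0.07 in place of 0.19. Without GFP embryo 3, 0 members rose, and without GFP embryo 5, 4 did.

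The maternal and germ plasm list had 44 measured genes, of which 40 were lower in Nkx2-5+GFP embryos. Of the 44, 0 rose, 7 fell and 37 did not pass, and adjusted over the list alone 1 rose and 13 fell. The list stood below other genes (camera adjusted p = 3.87e-06), with an adjusted p of 0.133 with an estimated correlation. grip2.L, a germ plasm gene, fell by 0.54 on the log2 scale, mos.L, the kinase gene of oocyte arrest, by 0.42 and tent2.S, a poly(A) polymerase gene, by 0.28. Without GFP embryo 3, 0 members fell, and without GFP embryo 5, 11 fell.

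Cell cycle genes, 65 measured, had 2 that rose, 7 that fell and 56 that did not pass, and adjusted over the list alone 6 rose and 19 fell. The list stood below other genes (camera adjusted p = 0.0319), with an adjusted p of 0.264 with an estimated correlation, of 0.0569 without GFP embryo 4, of 0.0556 without Nkx2-5+GFP embryo 3 and of 0.0972 without the dimmer probe sets. The replication licensing gene cdc6 fell in both copies, by 0.43 for cdc6.L and by 0.69 for cdc6.S, and the mitotic kinase gene aurkb.S fell by 0.48 on the log2 scale. gins1.S, a replication gene, rose by 0.72. Without GFP embryo 3, 2 members fell, and without GFP embryo 5, 17 fell and 4 rose. Without GFP embryo 2, 0 members rose.

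Ribosomal protein genes were higher in 72 of 73 measured members, with a mean log2 difference of 0.31 ± 0.13 (SD over genes) that lay between 0.27 and 0.37 over the alternatives fixed beforehand. Of them 15 rose, 0 fell and 58 did not pass, and 42 rose when adjusted over the list alone. The camera adjusted p was 7.52e-21 with the preset correlation, while these genes were strongly correlated with each other among embryos, at an estimated 0.557, and the adjusted p was 0.157 with an estimated correlation. rpl37.S rose by 0.50, rpl35a.S by 0.49, rpl34.L by 0.42 and rpl4.L by 0.38. Without Nkx2-5+GFP embryo 1, 2 members rose, and without GFP embryo 5, 32 rose.

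In the Notch list, 23 measured, 4 rose, 1 fell and 18 did not pass, and adjusted over the list alone 7 rose and 2 fell. The hes genes encode repressors downstream of Notch, and hes5.5.S rose 2.14-fold, hes1.S 1.69-fold and hes2.L 1.53-fold. rbpj.S, the DNA-binding partner of the Notch receptor, fell by 0.45 on the log2 scale. The camera adjusted p was 0.00419, and the adjusted p was 0.133 with an estimated correlation. Without GFP embryo 3, 0 members rose.

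The Wnt list, 46 measured, had 4 rises, 0 falls and 42 that did not pass, and adjusted over the list alone 9 rose. The receptor genes fzd10.S, ror2.L and fzd2.S rose by 1.09, 0.76 and 0.56, and kremen2.S, which encodes a co-receptor of Dickkopf, by 0.88, with 0.51 to 1.18 over the alternatives fixed beforehand. The L copy, fzd10.L, differed by -0.24 and did not pass (limma adjusted p = 0.694). The camera adjusted p was 0.00694, and the adjusted p was 0.133 with an estimated correlation. Without GFP embryo 4, 1 member rose, and without GFP embryo 5, 7 did.

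Cell adhesion and movement genes, 49 measured, had 4 that rose, 0 that fell and 45 that did not pass, and 5 rose when adjusted over the list alone. The matrix protease gene mmp14.L rose by 0.97, the integrin gene itga3.L by 0.76 and the cadherin genes cdh11.S and cdh3.L by 0.67 and 0.30, and both cadherin calls were lost in most alternatives fixed beforehand. The camera adjusted p was 0.00522, and the adjusted p was 0.157 with an estimated correlation. Without GFP embryo 2, 3 or 6 or Nkx2-5+GFP embryo 1, 2 or 6, 0 members rose.

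Of 14 measured genes of p53 and apoptosis, 1 rose, 1 fell and 12 did not pass, and adjusted over the list alone 5 rose and 1 fell. ccng1.L, a cyclin gene induced by p53, rose by 1.12 and mdm4.S, an inhibitor of p53, fell by 0.38 on the log2 scale, a call lost in most alternatives fixed beforehand. The camera adjusted p was 0.00694, and the adjusted p was 0.133 with an estimated correlation. Without GFP embryo 5, 4 members rose. In the heat shock and stress list, 26 measured, 1 rose, 0 fell and 25 did not pass, and 2 rose when adjusted over the list alone. The rise was hspa5.L, the chaperone gene of the endoplasmic reticulum, by 0.81, while its copy hspa5.S differed by 0.49 and did not pass. The camera adjusted p was 0.00635, and the adjusted p was 0.133 with an estimated correlation. Without Nkx2-5+GFP embryo 5, 3 members of the stress list rose.

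For retinoic acid genes, 30 measured, the camera test pointed upward (adjusted p = 0.00694, and adjusted p = 0.178 with an estimated correlation), while 0 rose, 1 fell and 29 did not pass. The call of the list was also lost without the dimmer probe sets (camera adjusted p = 0.28). The fall was rdh10.S, a retinol dehydrogenase gene, by 0.55 on the log2 scale. Adjusted over the list alone 2 rose and 2 fell. Without GFP embryo 5, 2 members fell. Among 26 measured genes of blood and endothelium, 1 rose, 2 fell and 23 did not pass, and adjusted over the list alone 3 rose and 2 fell. The ETS factor gene ets2.S fell by 0.95 and tek.S, an endothelial receptor gene, by 0.72 on the log2 scale, while the apelin receptor gene aplnr.S rose by 0.51. The L copy, ets2.L, differed by 0.62 in the other direction and did not pass (limma adjusted p = 0.154). The ets2 copies differed from each other (limma adjusted p of the difference 0.0155). This list did not stand apart (camera adjusted p = 0.931, and adjusted p = 0.933 with an estimated correlation), and camera pointed upward where its mean and median, -0.03 and -0.02, were negative. Without GFP embryo 2, 0 members of the blood list rose.

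**Figure D2:**
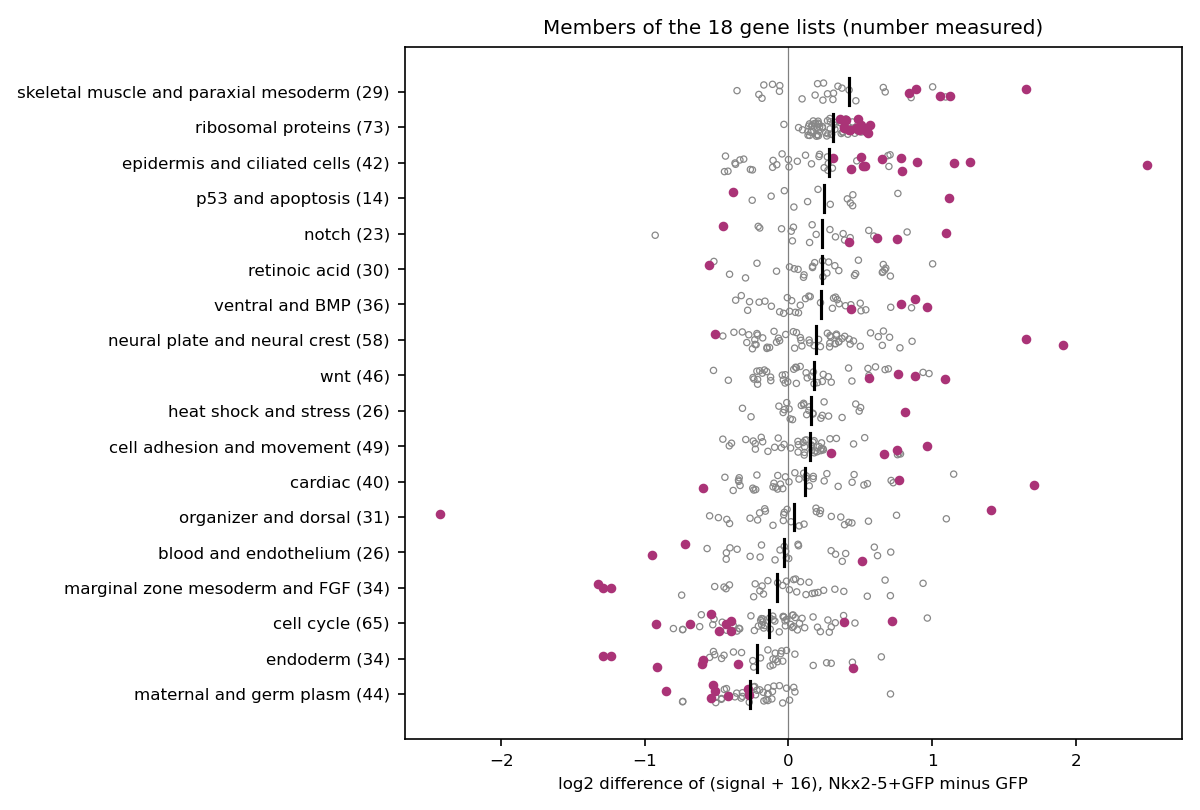
Log2 differences of (signal + 16), Nkx2-5+GFP minus GFP, of each measured member of the 18 lists, with the number measured after each name; filled points passed the adjusted threshold over all probe sets, open points did not, and black bars are list means. Epidermal genes hold 12 filled points to the right of 0 and maternal genes 7 to the left.

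The embryos also differed along a shared axis of variation. On the first axis computed from the GFP embryos alone, which held 46.6% of their spread, GFP embryos scored 0 ± 15.1 and Nkx2-5+GFP embryos 16.9 ± 7.83 (SD, n = 6 each, exact permutation p = 0.0368). The direction of the axis was set by the group difference, so the sign of this shift is not a result. The axis was not computed anew for each assignment, so the permutation p does not allow for its origin in the GFP embryos. With this score in the limma fit, 70 probe sets were called, 59 higher and 11 lower. Of the listed genes, 5 epidermal genes, irx4.L, fzd10.S and ccng1.L rose in that fit and nodal3.1.L and ets2.S fell, while 0 muscle, ribosomal or ventral genes rose and 0 maternal, endoderm or cell cycle genes fell. Camera passed 5 lists in that fit, those of epidermis, skeletal muscle, endoderm, maternal and ribosomal protein genes, and the ribosomal mean was 0.11. The beta-actin 3' to 5' ratio, a sign of RNA integrity, was 3.43 ± 0.64 in GFP and 2.98 ± 0.22 in Nkx2-5+GFP embryos (SD, n = 6 each, exact permutation p = 0.154). With this ratio in the fit 160 probe sets were called. Of the listed genes, 6 epidermal genes rose and 3 endoderm genes fell in that fit, while 0 ribosomal, ventral, adhesion, Notch or neural genes rose and 0 maternal genes fell. Sizes changed less than calls, with the median size of the changed probe sets at 96.5% of that without the ratio. The ribosomal mean was 0.27 in place of 0.31, the maternal mean -0.25 in place of -0.27 and the ventral mean 0.17 in place of 0.23. The endoderm and cell cycle lists no longer passed camera, the cell cycle list with an adjusted p of 0.0561. The array of Nkx2-5+GFP embryo 6 stood apart, with a 10th percentile signal of 24.3 where the others lay at 19.4 or below, and 510 probe sets were called without it.

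**Figure D3:**
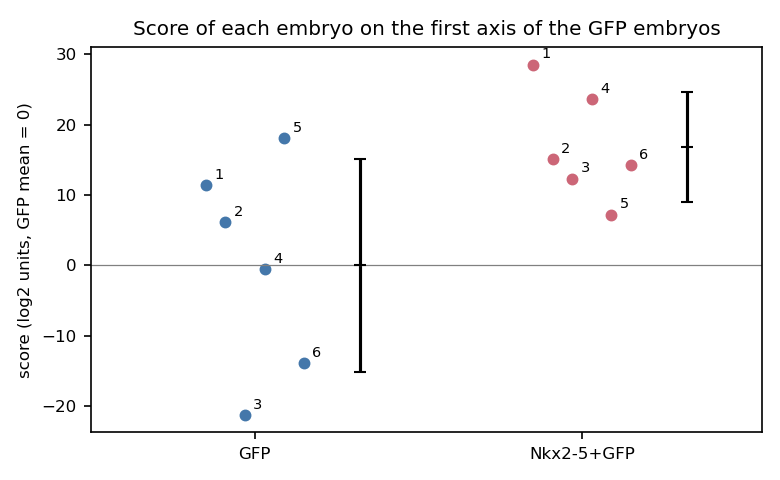
Score of each of the 12 embryos on the first axis of variation computed from the GFP embryos, in log2 units with the GFP mean at 0; numbers are replicate numbers and black bars the mean ± SD of each group. Nkx2-5+GFP embryos ranged from 7.23 to 28.6, and GFP embryos reached down to -21.2.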

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

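The tests on the shared axis, the 3' to 5' balance, the unnamed probe set of largest difference and the control probe set AFFX-Xl-M62653-1_s_at were chosen after the results were seen, and the comparison with other splits of the embryos was fixed before.

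Other splits of the 12 embryos into groups of 6 gave far fewer calls. Among 100 splits, only the real one reached 988 changed probe sets, so 1 of 100 was as large, and the highest of the others gave 3. For the larger of the higher and lower counts the real value was 505 and the highest other 2, and for changes of at least 2-fold 130 against 2, each with 1 of 100 as large. Such counts were thus rare among the 100 splits tried, of 462 possible ones, which argues against a chance division of the embryos. The splits do not separate the injected mRNA from another difference between the groups. For the gene lists past the threshold, 14 in the real split was also reached by 1 of 100, but another split gave 13, so many lists can pass camera with the preset correlation without the groups being those of the study.

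The genes that differed between the groups also varied together among embryos of one group. Across 7746 probe sets, which are not independent, the weights on the first GFP axis correlated with the group difference at r = 0.627. Over the 18 lists, some of which share genes, the rank correlation was 0.581 (permutation p over lists = 0.0136). List means were taken here over members among these brighter probe sets only. All lists were measured in the same embryos, so this p does not measure the spread between embryos. The first axis of the Nkx2-5+GFP embryos correlated with the group difference at 0.489. Each axis was turned to make its correlation across probe sets positive, and its embryos also enter the group difference. Values for other splits of the embryos are not given here, so the r to be had without a change is not known. A candidate explanation for the shared variation is that the embryos differed in something other than the injected mRNA, such as their exact age. The score also went with array measures. GFP embryos 3 and 6 had the lowest scores, -21.2 and -13.9, and the highest median signals, 340 and 346. Nkx2-5+GFP embryos 1 and 4 had the highest scores, 28.6 and 23.7, and the lowest median signals, 313 and 302. The GAPDH 3' to 5' ratio was highest in GFP embryo 3, at 47.3, but 25.9 in GFP embryo 6. RNA or array quality was not separated from age. Nkx2-5 could itself move embryos along the GFP axis, and the design cannot separate these. With the score in the fit, 70 probe sets were still called. The median size of the changed probe sets went from 0.61 (median SE 0.14) to 0.37 (median SE 0.15), so sizes shrank to 60.7%. The axis came from 6 embryos and held 46.6% of their spread, so the score can measure such a factor only in part. The calls left in this fit therefore do not decide whether the factor was the whole cause. When only the differences of that fit were put in place of those without the score, 196 of 988 calls were left, and with only its SE and degrees of freedom 852, so most calls ended because sizes shrank. A different 3' to 5' balance stays open. With the actin ratio in the fit the median size of the changed probe sets was 96.5% of that without, but 160 probe sets were called, and 0 probe sets went with the ratio itself (limma, Benjamini-Hochberg over all probe sets), so this covariate could hardly move the differences and the test decides nothing. With only the SE of that fit put in place, 194 calls were left, with only its differences 854 and with only its degrees of freedom 866, so most calls ended because the SE grew, from a median of 0.14 to 0.16.

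A probe set that carries no gene name here, and that shares its cluster number with probe sets of hbg1.L and tuba5.S, had the largest difference of all, from 9.20 ± 3.37 to 1021 ± 254 (SD, n = 6 each), a log2 difference of 5.34 (limma adjusted p = 3.05e-11). The GFP signal lies below the 10th percentile of the arrays, so the size depends on the pseudocount, and it was 6.67 with a pseudocount of 1 and 3.86 with one of 64. Globin genes switched on in the embryo are argued against, since the highest log2 difference among 8 globin probe sets was 0.30, and so is cross-hybridisation from the bright probe sets that share its cluster number, which differed by at most 0.49. A candidate source is a sequence carried by the injected Nkx2-5 mRNA, as the lowest Nkx2-5+GFP signal was 686 and the highest GFP signal 14.9. The sequence of the construct was not used here, so this stays open.

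The control probe set AFFX-Xl-M62653-1_s_at was dimmer in every Nkx2-5+GFP embryo, at 9443 ± 1698 against 16704 ± 1311 (SD, n = 6 each), a log2 difference of -0.84 (limma adjusted p = 0.00192 over the control probe sets). The files do not say what it detects, and it may detect the injected GFP mRNA, but a GFP control probe set, AFFX-Xl-pd2EGFP_at, read 198 and 206 in the groups. A difference in scaling or hybridisation was tested first on the other bright control probe sets, of which AFFX-Xl-AF292560-1_s_at also fell, at -0.60, so the test left both explanations open. The 12 bright bacterial and phage spike-in probe sets, looked at only after that test had come out open, differed by -0.08 to 0.16. A scaling difference that moved all probe sets alike would have moved these too, so their values argue against one of -0.84. This second look was not fixed beforehand and does not say what AFFX-Xl-M62653-1_s_at detects. Why it and AFFX-Xl-AF292560-1_s_at fell stays open.

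Single embryos lay far from the rest of their group in 7 of 158 groups checked, where chance gives 7.9. GFP embryo 3 had an olfm4.L signal of 158, the others 382 to 618, and a GAPDH 3' to 5' ratio of 47.3, the others 23.0 to 29.9. Nkx2-5+GFP embryo 4 had signals of 1380 for sult6b1.5.L, the others 529 to 746, and of 2573 for aplnr.S, the others 1570 to 1872. Nkx2-5+GFP embryo 5 had 961 for fignl1.L, the others 503 to 624, and embryo 1 had 3052 for ror2.L, the others 2064 to 2373. The bioB spike-in of Nkx2-5+GFP embryo 6 read 939.8, the others 423 to 507. Among control probe sets outside the comparison, AFFX-Xl-a1Act-3_s_at, named for an actin, averaged 354 in Nkx2-5+GFP embryos, above the GFP range of 4.11 to 116. It differed by 2.81 on the log2 scale (limma adjusted p = 0.0137 over the control probe sets). The related AFFX-Xl-a1Act-M_s_at and AFFX-Xl-a1Act-5_s_at differed by 1.12 and 0.16 and did not pass. AFFX-Xl-AJ002682-2_s_at averaged 195, above the GFP range of 44.7 to 76.8.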

How the results depend on the processing

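The covariates were chosen after the data were seen, and the other alternatives before. No called value changed direction. Of the 72 named probe sets that passed, 28 passed in each alternative fixed before that tested them. Among these were itln1.L, krt12.4.S, nodal3.1.L, mix1.L, mix1.S and myf5.L, but nodal3.1.L was too dim to be tested without the dimmer probe sets. Changes of at least 2-fold numbered 66 with a pseudocount of 64, which compresses differences, and 45 without the dimmer probe sets, where fewer were tested. Without the intensity trend the counts were 437 changed, 254 higher and 183 lower, with 37 of the 72 named probe sets and 0 nkx2-5 probe sets called, and 0 nkx2-5 probe sets were called with array weights. The cause was not tested. Median scaling gave 523 higher and 369 lower. With the replicate number as a block, 779 probe sets and 0 nkx2-5 probe sets were called. Same-numbered embryos correlated at -0.337 to 0.31, above 0.1 for 4 numbers, and 2 numbers matched best with their own, so the numbers were not taken as pairs. With 1 embryo left out, changed probe sets ranged from 285 to 1485, higher from 179 to 700, lower from 106 to 842, 2-fold changes from 87 (without Nkx2-5+GFP embryo 1) to 213 (without GFP embryo 5), named probe sets called from 28 to 71, nkx2-5 probe sets from 0 to 2 and lists from 13 to 14. With the axis score the counts were 70 changed, 59 higher, 11 lower, 40 at least 2-fold, 13 named, 0 nkx2-5 and 5 lists. With the actin ratio they were 160, 119, 41, 71, 24 and 0, and 12 lists. Of the 18 lists, 14 passed camera with the preset correlation, 0 with an estimated correlation, where the smallest adjusted p was 0.121 and 6 had an unadjusted p under 0.05, and 11 passed fry, which tests a list against no change and not against other genes. Without the dimmer probe sets, 10 lists passed camera, and those of ventral, neural, cell cycle and retinoic acid genes no longer did. Signals near the 10th percentile, at 16.9 to 24.3, limit what dim probe sets can show.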

Other observations

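The tests in this part were chosen after the results were seen. With the axis score in the limma fit, epidermal genes were among the 70 called. itln1.L rose by 2.45 and krt12.4.L by 0.99. Outside that list's measured probe sets, cd81.L rose by 1.51 and 1 probe set of otogl2.L by 1.70, while the brighter otogl2.L probe set that stands in the list differed by 0.27 without the score and did not pass (limma adjusted p = 0.118). mmp3.L, a matrix protease gene, rose by 2.61, while nodal3.1.L fell by 2.02 and dand5.S, a Nodal antagonist gene, by 0.74 on the log2 scale. cfap52.S, a cilium gene, rose by 0.93. Of the 70, 65 were also called without the score.

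Over 1017 pairs measured for both copies, the log2 differences correlated at r = 0.42 across genes, which are not independent replicates (permutation p = 0.0001 from re-pairing the genes, the smallest that 10000 resamples can give). Both copies were called in 13 pairs, all 13 in a common direction, where independent calls give 4.88, a comparison that leaves out what all genes of an embryo share. Where exactly 1 copy was called, the other had the same sign in 99 of 118 pairs. Copies also correlated when the embryos were grouped otherwise, with a median of 0.169 over the other splits into groups of 6, and 8 of all 462 splits, the real one included, gave a correlation as large as 0.419. A shared response of the copies, probes that detect both and the shared axis of variation could each add to this correlation, and they were not separated. The copies differed from each other in 11 pairs at an adjusted p under 0.05 in limma and in 173 at an unadjusted p under 0.05. For cd81 the L copy rose by 1.68 and the S copy differed by -0.09 (limma adjusted p of the difference 0.006), and for fermt1 the S copy rose by 1.69 and the L copy differed by 0.11 (limma adjusted p of the difference 0.0232). For rdh10 the S copy fell by 0.55 on the log2 scale and the L copy differed by 0.32 (limma adjusted p of the difference 0.0155).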
